A study of Mus musculus with 8 samples.

How the data were processed

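Gastric RNA from male INS-GAS mice of the FVB/N background was measured on 8 one-colour Agilent mouse arrays. INS-GAS mice carry a transgene that makes gastrin under the insulin promoter. All animals were infected with Helicobacter pylori for 28 weeks, and a subcutaneous pellet was in place for the last 12 weeks of that time, from week 16 on. The pellet held 0.25 mg of 17β-estradiol (n = 3), 15 mg of tamoxifen (n = 2) or 5 mg of placebo (n = 3). Groups and replicate numbers were taken from the labels. The design text speaks of 9 samples while giving group sizes that sum to the 8 arrays analysed here. The labels do not say in so many words that each array holds a different mouse, so the p-values measure the spread between these samples.

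Total RNA was taken from longitudinal strips of stomach with Trizol and a column kit with DNase treatment, and the labelled material carried Cy3, per the labels' protocols. Such a strip holds the mucosa with the wall beneath it and, in a mouse, can include the squamous forestomach. Each array was read by Agilent Feature Extraction 9.1, per the labels. The deposited scanner files give, for every spot, a processed signal, which is an intensity on a linear scale that Feature Extraction had background-subtracted and detrended within the array, per the file headers. These intensities were not normalized between arrays and can be negative. The same files hold raw mean spot and local background intensities and yes or no flags for spots well above background, saturated or outlying. A second deposited table, the authors' series matrix, also holds intensity values. Within each array its values ranked as the raw median spot signal did, and its 8 columns had nearly one distribution, with medians of 179.8, 180.0 and 180.1 for estradiol 1 to 3, 179.7, 180.2 and 179.8 for placebo 1 to 3, and 179.9 and 180.2 for tamoxifen 1 and 2. The values are on a linear scale and have no direction to settle, since each array has 1 colour. The step that made the columns alike is not given in the sources used here. This table served only as an alternative.

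Every array had 45018 spots. Of these, 43379 were not controls, and they made up 41174 probes. The spots of a probe were averaged, with spots flagged as outliers included. A probe with every spot flagged on at least 1 array was not used, which left out 586 probes. Only the normexp alternative left flagged spots out of the average. Between 63.4% and 69.5% of the probes of an array were well above background, and the 75th percentile of the processed signal lay between 734 and 1112 intensity units. The number of arrays limits the precision. Each signal was divided by the 75th percentile of its array, set to at least 0.0159 of that percentile, and taken to log2. That floor was chosen after a higher one was seen to leave features with no variance. It is reached on at least 1 array by 1943 of the genes tested. Probes well above background on at least 2 arrays were kept (28847 probes), and of a gene's kept probes the one with the highest mean over all arrays stood for the gene. This gave 19279 genes, of which 3010 are features with no gene name and 6592 had several kept probes. Probe names came from the files and were updated through a RefSeq gene table of mouse assembly GRCm38: 23374 probes matched by accession, 6733 by symbol and 2919 by an older symbol, 1845 kept the name in the file and 6303 had no gene name. The array files were used without coordinates.

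The 3 group means were fitted to all 8 arrays together with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided moderated tests), so the groups share 1 estimate of the spread. Tables were read with the R package data.table, version 1.17.8, and figures were drawn with matplotlib 3.10.9. p-values were adjusted by the Benjamini-Hochberg method over the 19279 genes of a comparison, with a threshold of 0.05. Fold changes are differences of group means on the log2 scale with their standard errors (SE). Where a gene was not well above background on any array of one group, its fold change is a bound: the mean of the brighter group against the mean, over the arrays of the dimmer one, of the higher of the gene's own signal and the lowest signal among probes well above background. Such values, which hold for the main processing only, are written as "at least". So are those of Rapgef4 and Cxcl15 against a placebo mean with 2 arrays at the floor. Within this processing the floor can only lower the rise, but other background handling gave smaller rises for Rapgef4. In Nos1, Plin1 and Gast 1 placebo array stood at the floor, so their fold changes and SE are uncertain. Genes that share near-identical sequence with relatives, such as Ccl21a and its copies, cannot be told from them by a probe.

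Before the data were examined, 34 gene lists were fixed, covering pathways, gastric and immune cell types and other tissues that a strip can hold. They had 565 members, of which 553 were on the array and 493 measured. A list needed 5 measured members, which left 33 lists; the red blood cell genes, with 4 measured members, were not tested. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 33 lists. Beside it stand camera with a correlation estimated from the residuals, and fry, which tests whether a list's genes move one way on balance without comparing them with other genes. The genes named in the text followed a rule fixed at the same time. For each treatment against placebo these are the 6 largest rises and the 6 largest falls among genes past the threshold with no overlap between the groups and a proper gene symbol. Where fewer passed, the rule takes those with the smallest unadjusted p among genes changed at least 2-fold without overlap. It adds the 2 to 4 members with the smallest p of each list described, and always Esr1, Esr2, Pgr, Cxcl1, Il1b, Tnf, Ifng, Gast, Atp4a and Muc6. The direct comparison of the treatments used 4 and 4. Esr2 and Pgr were on the array but did not pass the background filter. The values of 1 gene are not reported here.

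The scan headers place the arrays on 3 slides, with replicate 1 of each group on slide 1, replicate 2 on slide 2, and estradiol 3 and placebo 3 on slide 3. Each slide was 1 scan, so slide, scan and replicate number are the same block. Within slides, estradiol always had the same array position, as had placebo and tamoxifen, so position on the slide and group cannot be told apart. Results are also given with slide as a block and within each slide.

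The likeness of the effects of both treatments was measured as the correlation and the covariance of their log2 fold changes across genes. Both comparisons use the same 3 placebo arrays, so the values lie above 0 with no effect at all. In 100 simulations each array was a random combination of the residuals of the fit, which keeps the measured covariance between genes and leaves no group difference. This replaced a first simulation whose arrays were linearly dependent. The arrays used here are still dependent, since residuals from 3 group means span fewer dimensions than there are arrays. The simulated range is therefore a rough guide. The fit and the list test were run on simulated log2 values of 19279 genes with independent noise, with 50 genes changed at each fold. Background correction, the floor, the filter and the choice of probe were not covered, and genes of real arrays vary together. For estradiol against placebo the fit recovered 42% of the genes changed 2-fold, 94% of those changed 4-fold, 98% at 8-fold and 100% at 16-fold. For tamoxifen against placebo it recovered 28%, 88%, 98% and 100%. Of the 179 and 166 genes that passed in these comparisons, 12 and 9 were unchanged. In each of them 2 lists passed, where only the cell cycle genes had been shifted.

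The alternatives fixed in advance were normexp background correction with an offset of 50, quantile normalization, median centring, the series matrix, no filter and a stricter filter on dim probes, every probe by itself, the mean of a gene's probes, fits of only the arrays of the groups compared, the slide block, eBayes with trend and robust, array weights, an estimated correlation for the list test, and each array left out in turn. Another floor (0.5 and 2 times its value), keeping the probes left out for outlier flags and the squamous list mean as a covariate were added after the data had been seen. A block for the day of scanning was not run, because all scans fell on the same day.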

Results

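The data are transcript levels in stomach strips of male INS-GAS mice infected with Helicobacter pylori and given estradiol, tamoxifen or placebo pellets. The design names placebo as the control of either treatment. There were 3 estradiol arrays, 2 tamoxifen arrays and 3 placebo arrays, and 19279 genes were tested. Pairs of arrays of the same group correlated at 0.977 to 0.986 across genes, and pairs from different groups at 0.973 to 0.989, so no array was a copy of another. All p-values for genes are from limma, and p-values for gene lists are from camera unless another test is named.

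The first comparison asked what 17β-estradiol did to gene expression in the infected stomach. Estradiol raised 13 genes and no gene fell past the threshold. The largest rise was that of Cfd, which encodes adipsin, a complement protease that fat cells secrete: its log2 fold change was 5.43 ± 0.59 (SE, n = 3 and 3), or 43.1-fold (adjusted p = 0.0450). Ccl21a, a chemokine that guides lymphocytes and dendritic cells, rose by 2.22 ± 0.20 (4.66-fold, adjusted p = 0.0330). Cilp, a matrix protein first described in cartilage, rose by 1.90 ± 0.20, and Abca8a, a membrane lipid transporter, rose by 1.82 ± 0.18.

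Otor, which encodes a secreted protein of the inner ear, was not well above background on any placebo array and rose at least 3.28-fold with estradiol (adjusted p = 0.0132). Rapgef4, an exchange factor activated by cyclic AMP, rose at least 3.11-fold (adjusted p = 0.0330), since 2 of the 3 placebo arrays stood at the floor of the scale. The log2 fold change of Otor was 0.88 with normexp background correction, 0.59 in the series matrix, 0.72 with 2 times the floor and 2.71 with 0.5 times, against 1.72, and that of Rapgef4 0.69, 0.41 and 0.66 in the first 3 of these, against 1.64. Those of Cilp and Abca8a were 1.15 and 1.01 with normexp and 1.055 and 0.71 in the series matrix. The other 7 had fitted log2 fold changes between 1.07 and 2.43. They include 3 features with no usable gene symbol, and Adamtsl3, Igfbp6 and Tmeff2, which are named here after their values were seen; Adamtsl3 and Tmeff2 were not well above background on any placebo array. Each of the 13 was higher on 3 of 3 slides, which is no separate evidence, since the same arrays picked them. With slide as a block none of the 13 passed, with adjusted p between 0.0806 and 0.115, and limma called 0 genes then, with 2994 at an unadjusted p under 0.05; normexp also left 0, with 1881. Leaving out 1 array at a time left between 0 and 36 genes past the threshold: 0 without estradiol 1, without estradiol 2 or without either tamoxifen array, 1 without placebo 2, 3 without placebo 1, 4 without estradiol 3 and 36 without placebo 3.

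At an unadjusted p under 0.05 there were 2799 genes, 1840 of them higher and 959 lower, where 964 would be expected by chance. The groups did not overlap for 4067 genes (21.1%, where chance gives 10%), and 416 of these differed at least 2-fold, 337 higher and 79 lower. The genes nearest to the threshold among those lower with estradiol did not pass. Angptl4, an inhibitor of lipoprotein lipase, had a log2 fold change of −1.57 ± 0.18 (adjusted p = 0.0528), Fosl1, a subunit of the transcription factor AP-1, −1.46 ± 0.19 (0.0621), and Gch1, which makes the tetrahydrobiopterin needed for nitric oxide synthesis, −1.19 ± 0.16 (0.0755). Tnfrsf23, a decoy receptor for TRAIL, stood at −1.24 ± 0.19, Cidea, a lipid droplet protein, at −1.28 ± 0.20 and Lhx5, a homeobox gene, at −1.46 ± 0.24. Each of these 6 was lower on 3 of 3 slides, which their choice as genes without overlap between the groups fixes. Median centring called 16 genes, 12 higher and 4 lower, against 13 and 0, and under it Angptl4, Fosl1 and Gch1 passed (adjusted p = 0.0425 each). Over all alternatives the adjusted p of these 3 ranged from 0.0347 to 0.380, from 0.0339 to 0.456 and from 0.0425 to 0.428. That centring moves the median log2 fold change of all genes by −0.125 with estradiol and by −0.142 with tamoxifen.

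**Figure D1:**
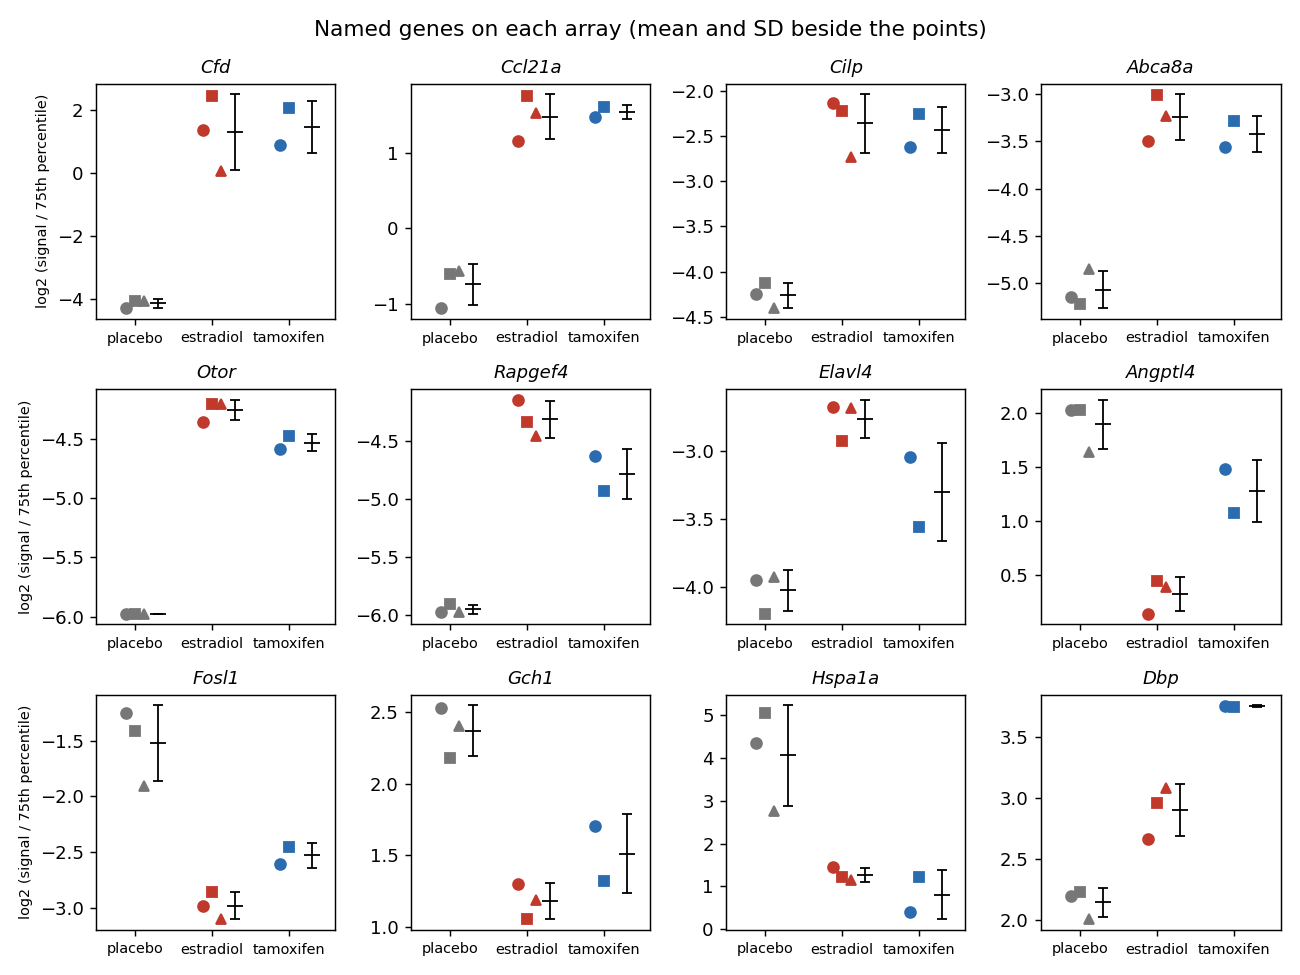
Log2 signal relative to the 75th percentile of the array (y axis) for 12 genes in the placebo, estradiol and tamoxifen groups. Each point is 1 array, its shape gives the slide (circle for slide 1, square for slide 2, triangle for slide 3), and the black bar beside the points is the group mean with its SD. Cfd lay between −4.28 and −4.05 on the 3 placebo arrays and between 0.06 and 2.46 on the estradiol arrays.

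Genes of the inflammatory response to the infection were measured as well. Cxcl1, a neutrophil-attracting chemokine, had a log2 fold change of −0.69 ± 0.16 with estradiol, was lower on 3 of 3 slides and did not pass over all genes (adjusted p = 0.187). It passed when adjusted over the list alone (adjusted p = 0.0132), as did 1 other of the 8 measured neutrophil-attracting chemokines and their receptor, Cxcl15, in the other direction, at least 5.74-fold higher with 2 of the 3 placebo arrays at the floor. Over all genes 0 of these 8 passed, and the list did not pass (adjusted p = 0.869); its median (0.15) and mean (0.25) were positive while the test pointed down. Cxcl15 is named after its value was seen. The cytokines Il1b (−0.08 ± 0.25), Tnf (−0.71 ± 0.56) and Ifng (0.67 ± 0.71) did not pass. Of 19 measured inflammatory cytokines and mediators, 0 passed over all genes and 4, all lower, when adjusted over the list alone (list adjusted p = 0.196). The estrogen receptor gene Esr1 stood at 0.42 ± 0.30, and the list of estrogen receptors and estrogen target genes, 8 higher and 8 lower, did not pass (adjusted p = 0.600).

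Of 33 gene lists, 11 passed with estradiol, 5 higher and 6 lower. With an estimated correlation 0 passed, and the lowest adjusted p was 0.152; fry called 1 list, the acute heat-shock and stress genes. The squamous forestomach markers, which are keratins and cornification genes, rose as a list, with 19 of 21 higher (adjusted p = 3.31e-06; adjusted p = 0.588 with an estimated correlation). Their median log2 fold change was 2.15. None passed over all genes, while 12 higher and 2 lower passed when adjusted over the list alone. Examples are the keratins Krt6b at 2.19 ± 0.41 and Krt13 at 2.68 ± 0.54 and the cornified envelope gene Sprr3 at 2.58 ± 0.61. Ivl, which encodes involucrin of the same envelope, stood at −2.17 ± 0.45. The list's mean difference was −0.15 on slide 1, 2.37 on slide 2 and 3.06 on slide 3, and its call held with slide as a block (adjusted p = 7.49e-05).

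The smooth muscle markers rose as a list, with 12 of 13 higher (median 0.75, adjusted p = 1.89e-05; adjusted p = 0.566 with an estimated correlation). Of the 13, 0 passed over all genes and 8, all higher, when adjusted over the list alone. Examples are the contractile genes Mylk (0.84 ± 0.20), Myl9 (0.90 ± 0.24) and Des (0.99 ± 0.26). The enteric neuron and glia markers rose too, with 10 of 11 higher (median 1.22, adjusted p = 1.89e-05; adjusted p = 0.418 with an estimated correlation). When adjusted over the list alone 6 members passed, all higher. Elavl4, an RNA-binding protein of neurons, stood at 1.26 ± 0.17 and Nos1, the neuronal nitric oxide synthase, at 2.11 ± 0.57. Within slides the smooth muscle mean differed by −0.04, 1.04 and 0.92 and the neural mean by 0.58, 0.67 and 2.01 on slides 1, 2 and 3; both calls held with slide as a block (adjusted p = 0.000142 and 1.23e-05). Compared as 1 mean per array, the shifts were 2.46 SE (squamous), 2.63 SE (smooth muscle) and 2.51 SE (neural) against a 95% limit of 2.57, and with slide as a block 2.03, 2.27 and 2.85 SE against 3.18.

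Per array, relative to the mean of the placebo arrays, the squamous mean was 0.78, 2.46 and 2.03 on estradiol arrays 1 to 3 and 0.94, 0.09 and −1.03 on placebo arrays 1 to 3. Placebo 1 had the highest and placebo 3 the lowest squamous mean of its group, and the same held for the neural mean (0.65 and −0.91). Smooth muscle markers stood at 0.51 on placebo 1 and at −0.28 and −0.23 on the others. With the squamous mean as a covariate, an alternative chosen after seeing the data, 0 genes passed with estradiol. The call of Cfd was lost at a log2 fold change of 5.56 (adjusted p = 0.380, the highest of a range from 0.0425), as were those of the smooth muscle (0.281; mean 0.18 against 0.64 without the covariate), endocrine (0.270; 0.17 against 0.74), cell cycle (0.974; −0.04 against −0.19) and adipocyte lists (0.0768; 1.18 against 1.30).

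The adipocyte markers rose as a list with estradiol (7 of 11 higher, median 0.90, adjusted p = 0.0176; adjusted p = 0.559 with an estimated correlation). Cfd was the 1 member that passed over all genes. When adjusted over the list alone 6 higher and 2 lower members passed. Adipoq, the fat cell hormone adiponectin, was not well above background on any placebo array and stood at least 14.3-fold higher (adjusted p = 0.132). That bound holds for the main processing: over the alternatives the log2 fold change of Adipoq ranged from 2.00 to 4.83. Car3, an abundant carbonic anhydrase of fat and muscle, stood at 2.45 ± 0.63, although its second probe gave 0.07. Cidec, a lipid droplet gene, stood at −0.59 ± 0.12. The list's mean differed by 1.16, 1.86 and 0.90 on slides 1 to 3 (adjusted p = 0.0384 with slide as a block). The skeletal muscle markers did not pass (adjusted p = 0.0664), and estradiol 2 stood apart in them, at 3.11 against 0.25 and −0.02 on the other estradiol arrays. The gastric endocrine cell markers rose as a list, with 11 of 12 higher (median 0.65, adjusted p = 0.0176; adjusted p = 0.418 with an estimated correlation). Ghrl, which encodes ghrelin, stood at 0.59 ± 0.16 and Scg5, a granin-family chaperone of secretory granules, at 0.71 ± 0.20. These 2 passed when adjusted over the list alone, and 0 over all genes. Their mean differed by 0.39, 1.25 and 0.58 within slides (adjusted p = 0.0154 with slide as a block). Gast, the gastrin gene, stood at 2.81 ± 2.39, with 3.27 on estradiol 2 and no more than −2.80 on the other estradiol arrays.

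Markers of mucous cells, intestinal epithelium and metaplasia fell as lists with estradiol. All 10 surface and neck mucous cell markers were lower (median −0.44, adjusted p = 0.000689; adjusted p = 0.418 with an estimated correlation). Tff2, a trefoil peptide of mucous neck cells, stood at −0.53 ± 0.21, Gkn1, a gastrokine of surface cells, at −0.55 ± 0.22 and Muc6, the mucin of neck cells, at −1.25 ± 0.50. The intestinal epithelial markers fell as a list, with 10 of 12 lower (median −0.53, adjusted p = 0.0176; adjusted p = 0.566 with an estimated correlation). Lgals4 stood at −0.55 ± 0.17 and the brush-border phosphatase gene Alpi at −1.92 ± 0.78. The metaplasia-associated genes fell as a list, with 9 of 11 lower (median −0.34, adjusted p = 0.0262; adjusted p = 0.559 with an estimated correlation). Cldn7, a tight junction gene, stood at −1.26 ± 0.51 and Olfm4, a stem cell marker of the intestine, at −1.34 ± 0.60, although its second probe gave 0.21. In these 3 lists 0 members passed over all genes and 0 when adjusted over the list alone. Their means differed by −0.49, −0.66 and −0.29 (mucous), −0.60, −1.24 and 0.14 (intestinal) and −0.55, −0.27 and −0.24 (metaplasia) on slides 1 to 3. With slide as a block the adjusted p was 0.000531, 0.0196 and 0.0166.

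The acute heat-shock and stress genes fell as a list, with 11 of 12 lower (median −0.51, adjusted p = 3.23e-05; adjusted p = 0.152 with an estimated correlation; adjusted p = 0.0226 by fry). Hspa1a and Hspa1b, which encode inducible heat-shock chaperones, stood at −2.79 ± 0.55 and −2.81 ± 0.56, and their co-chaperone Dnajb1 at −0.92 ± 0.20. Of the 12, 0 passed over all genes and 4, all lower, when adjusted over the list alone. The xenobiotic metabolism genes fell as a list, with 11 of 15 lower (median −0.35, adjusted p = 0.000551; adjusted p = 0.418 with an estimated correlation). The glutathione transferase genes Gsta3 (−0.78 ± 0.21), Gsta4 (−0.49 ± 0.14) and Gsta1 (−0.60 ± 0.19) are examples. The cell cycle genes fell as a list, with 22 of 30 lower (median −0.25, adjusted p = 0.00696; adjusted p = 0.867 with an estimated correlation). Birc5, the mitotic regulator survivin, stood at −0.53 ± 0.22 and Mki67, a proliferation marker, at −0.40 ± 0.19. In both of these lists 0 members passed over all genes and 0 when adjusted over the list alone. Within slides 1, 2 and 3 the means differed by −0.78, −0.91 and −0.75 (heat shock), −0.28, −0.56 and 0.02 (xenobiotic) and 0.10, 0.03 and −0.71 (cell cycle), and with slide as a block the adjusted p was 9.42e-05, 0.00187 and 0.00568. Of the 11 list calls with estradiol, 5 were lost when a single array was left out: the cell cycle genes without estradiol 3 (adjusted p = 0.335) or placebo 3 (0.309), the adipocyte and endocrine markers without placebo 3 (0.0704 each), the intestinal markers without placebo 2 (0.0723), and the metaplasia-associated genes without estradiol 1 (0.120), placebo 1 (0.0952) or placebo 2 (0.0647).

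The other 22 lists did not pass with estradiol. Those of immune cells were T cell markers (16 of 19 higher, adjusted p = 0.169), B cell markers (adjusted p = 0.434), plasma cell markers (0.360), macrophage and monocyte markers (0.192), neutrophil markers (0.882), mast cell and eosinophil markers (0.122), MHC class II presentation (0.511), interferon-stimulated genes (0.511) and other chemokines (0.600). Those of the glands were parietal cell markers (0.618), with the proton pump gene Atp4a at 0.50 ± 0.51, and chief cell markers (0.627). The remaining lists were pancreatic acinar markers (0.0664), fibroblast and matrix genes (0.120), immediate-early genes (0.122), Wnt target and pathway genes (0.125), cholesterol synthesis genes (0.315), endothelial markers (0.421) and epithelial host-defence genes (0.869). The neutrophil and chief cell lists had a negative median and a positive mean, as had the epithelial host-defence genes. The estrogen target list had a positive median and a negative mean, and the other chemokines a positive median and mean with a test that pointed down. When adjusted over the list alone, 2 endothelial genes passed, both higher, and 1 immediate-early gene, Ier3, at −0.65 ± 0.14. The endothelial genes are Cldn5 (1.34 ± 0.29) and Vwf (0.81 ± 0.22), named after their values were seen.

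**Figure D2:**
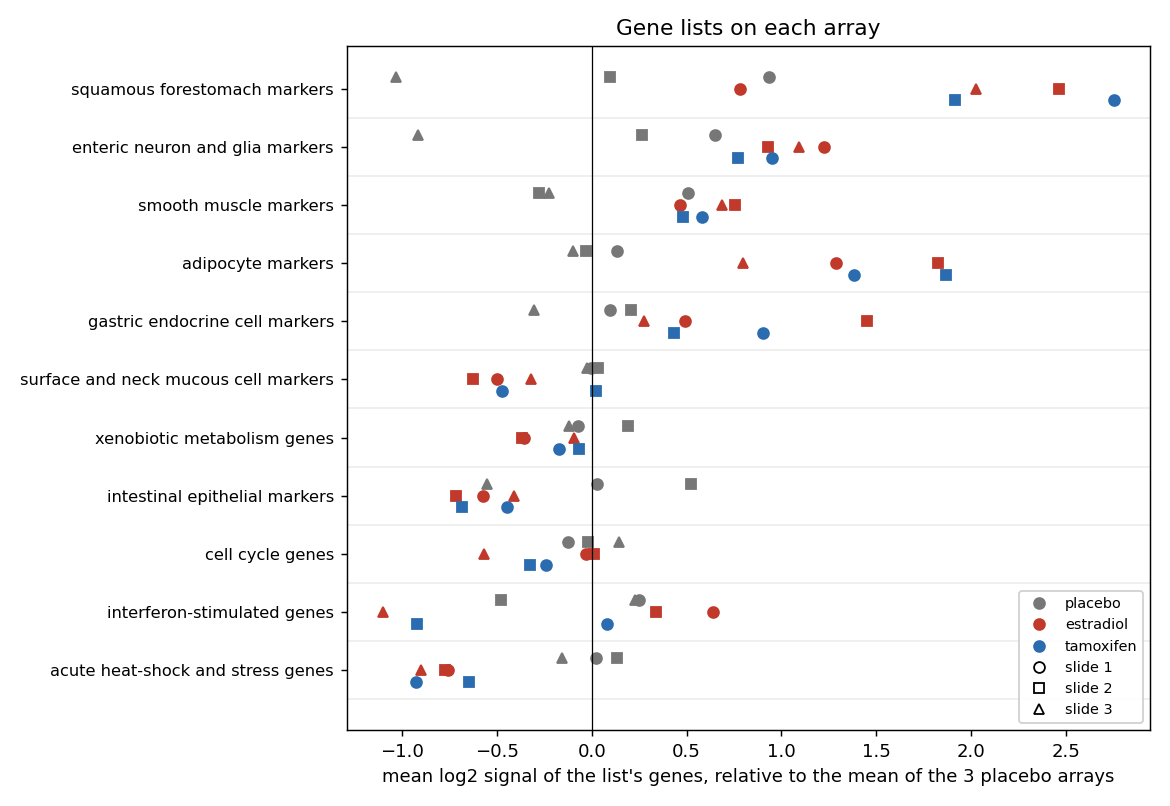
Mean log2 signal of the measured genes of 11 gene lists on each array, relative to the mean of the 3 placebo arrays (x axis). Each point is 1 array, coloured by group and shaped by slide. The squamous mean of estradiol 1 (0.78) lay below that of placebo 1 (0.94), and the heat-shock means of the 5 treated arrays, from −0.93 to −0.65, lay below the placebo arrays, from −0.16 to 0.13.

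The second comparison asked the same of tamoxifen, which binds the estrogen receptor and acts as an antagonist or a partial agonist depending on the tissue. With 2 arrays no gene passed: limma called 0 genes, with 1975 at an unadjusted p under 0.05 (1288 higher and 687 lower, 964 expected by chance). The lowest adjusted p was that of Otor (0.0981), which was not well above background on any placebo array and stood at least 2.72-fold higher. Ccl21a stood at 2.28 ± 0.23 (SE, n = 2 and 3; adjusted p = 0.111), Dbp, a clock-controlled transcription factor, at 1.61 ± 0.16 (0.111), Cfd at 5.61 ± 0.65 (0.187), Abca8a at 1.64 ± 0.20 and Cilp at 1.83 ± 0.22. Dbp and Ccl21a passed under eBayes with trend and robust (adjusted p = 0.0235 each, the lowest of a range up to 0.889 over all alternatives), and Dbp in the series matrix (0.0331), whereas the median-centred and quantile-normalized values called 0 genes.

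Among genes lower with tamoxifen, Hspa1a stood at −3.26 ± 0.61 and Hspa1b at −3.03 ± 0.62, Nfil3, a repressor in the clock, at −1.07 ± 0.21, Fosl1 at −1.01 ± 0.21, Ccl2, a monocyte-attracting chemokine, at −1.19 ± 0.25 and the vomeronasal receptor gene Vmn2r30 at −1.32 ± 0.23, with adjusted p between 0.354 and 0.368. Cxcl1 stood at −0.90 ± 0.17 (adjusted p = 0.365), Il1b at −0.22 ± 0.28, Tnf at −0.86 ± 0.62, Ifng at −0.09 ± 0.79, Esr1 at 0.63 ± 0.34, Gast at 3.27 ± 2.67, Atp4a at 0.39 ± 0.57 and Muc6 at −0.53 ± 0.56. The groups did not overlap for 4811 genes (24.95%, where chance gives 20%), and 477 of these differed at least 2-fold, 412 higher and 65 lower.

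Of the 33 lists 11 passed with tamoxifen, 5 higher and 6 lower; 0 passed with an estimated correlation (lowest adjusted p = 0.273) and 0 by fry. The squamous forestomach markers rose as a list, with 19 of 21 higher (median 2.74, adjusted p = 5.34e-11; adjusted p = 0.667 with an estimated correlation). Sprr3 stood at 3.50 ± 0.68, Krt13 at 3.09 ± 0.61 and Krt6b at 2.69 ± 0.46. When adjusted over the list alone 17 higher and 1 lower member passed. The smooth muscle markers rose as a list (12 of 13 higher, median 0.52, adjusted p = 0.000292; adjusted p = 0.667 with an estimated correlation), with Des at 1.03 ± 0.30 and Cnn1 at 1.12 ± 0.38 and 0 members passing when adjusted over the list alone. The enteric neuron and glia markers rose as a list (10 of 11 higher, median 0.80, adjusted p = 0.000292; adjusted p = 0.667 with an estimated correlation). When adjusted over the list alone 2 members passed, both higher, and Elavl4 stood at 0.73 ± 0.19. The adipocyte markers rose as a list (8 of 11 higher, median 1.046, adjusted p = 0.000625; adjusted p = 0.667 with an estimated correlation), and 5 members passed when adjusted over the list alone. Adipoq, not well above background on any placebo array, stood at least 21.5-fold higher (log2 fold change from 2.29 to 5.42 over the alternatives). Plin1, a coat protein of lipid droplets, stood at 2.24 ± 0.45. The endocrine markers rose as a list (11 of 12 higher, median 0.36, adjusted p = 0.0469; adjusted p = 0.667 with an estimated correlation), with Scg5 at 0.62 ± 0.22 and 0 members passing when adjusted over the list alone.

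Another 6 lists fell with tamoxifen. The cell cycle genes fell (23 of 30 lower, median −0.33, adjusted p = 0.000292; adjusted p = 0.691 with an estimated correlation), with the cyclins Ccnb1 at −0.81 ± 0.23 and Ccnb2 at −0.76 ± 0.26. The heat-shock and stress genes fell (11 of 12 lower, median −0.36, adjusted p = 0.000396; adjusted p = 0.273 with an estimated correlation), with Hsph1 at −1.56 ± 0.39 and Dnajb1 at −1.004 ± 0.229, and 4 lower and 1 higher member passed when adjusted over the list alone. The interferon-stimulated genes fell (27 of 29 lower, median −0.37, adjusted p = 0.00413; adjusted p = 0.875 with an estimated correlation), with Ifi44 at −1.19 ± 0.45 and Ifit1 at −1.12 ± 0.57. The intestinal epithelial markers fell (10 of 12 lower, median −0.51, adjusted p = 0.009996; adjusted p = 0.667 with an estimated correlation), with the lipid transfer gene Mttp at −0.97 ± 0.38 and the goblet cell peptide Tff3 at −1.42 ± 0.82. The mast cell and eosinophil markers fell (9 of 10 lower, median −0.43, adjusted p = 0.0195; adjusted p = 0.667 with an estimated correlation), with Cpa3, a mast cell protease, at −0.44 ± 0.26. The immediate-early genes fell (10 of 17 lower, median −0.13, adjusted p = 0.0469; adjusted p = 0.667 with an estimated correlation), with Atf3 at −0.56 ± 0.19 and Egr1 at −0.56 ± 0.24. Outside the heat-shock list, 0 members of these lists passed when adjusted over the list alone. Over all genes 0 members of any list passed with tamoxifen.

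Within slides 1 and 2, the tamoxifen differences were 1.82 and 1.82 (squamous), 0.07 and 0.76 (smooth muscle), 0.30 and 0.51 (neural), 1.25 and 1.90 (adipocyte), 0.81 and 0.23 (endocrine), −0.12 and −0.31 (cell cycle), −0.95 and −0.78 (heat shock), −0.17 and −0.44 (interferon), −0.48 and −1.21 (intestinal), −0.30 and −0.74 (mast cell) and −0.30 and −0.19 (immediate-early). With slide as a block these 11 calls held, with adjusted p from 5.16e-07 for the squamous to 0.0418 for the endocrine list, and 13 lists passed in all. The interferon mean rested on tamoxifen 2 (−0.92), since tamoxifen 1 stood at 0.08, and the call was lost without tamoxifen 2 (adjusted p = 0.868), placebo 1 (0.0788) or placebo 3 (0.0938). The mast cell call was lost without the same 3 arrays (0.868, 0.135 and 0.0521), the cell cycle call without placebo 3 (0.0815) and the intestinal call without placebo 2 (0.0534) or tamoxifen 2 (0.131). The endocrine call was lost without estradiol 1 (0.0547), placebo 1 (0.135), placebo 3 (0.108) or tamoxifen 2 (0.313). The immediate-early call was lost without estradiol 2 (0.0599), placebo 1 (0.280), placebo 2 (0.0534), tamoxifen 1 (0.0592) or tamoxifen 2 (0.0847). With the squamous mean as a covariate the smooth muscle mean turned to −0.08 (adjusted p = 0.457), and the neural (0.477; mean 0.00154 against 0.86 without the covariate), endocrine (0.527; −0.09 against 0.67), cell cycle (0.729; −0.07 against −0.28) and interferon (0.268; −0.23 against −0.42) calls were lost. The heat-shock call was lost (0.0767) at a mean of −0.81 against −0.79, so its shift stayed as large. Compared as 1 mean per array, the shifts were 2.93 SE (squamous), 1.96 SE (smooth muscle) and 1.79 SE (neural) against a 95% limit of 2.57, and with slide as a block 2.11, 1.47 and 1.42 SE against 3.18. Leaving out tamoxifen 1 raised the number of lists past the threshold to 20, and leaving out placebo 3 lowered it to 7.

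The other 22 lists did not pass with tamoxifen. Their adjusted p was 0.0704 for the xenobiotic metabolism genes, 0.114 for the surface and neck mucous cell markers, 0.131 for the metaplasia-associated genes, 0.137 for other chemokines, 0.218 for inflammatory cytokines and mediators, 0.311 for epithelial host-defence genes, 0.379 for neutrophil markers and 0.489 for fibroblast and matrix genes. It was 0.361 each for plasma cell markers, Wnt target and pathway genes and pancreatic acinar markers, and 0.531 for both chief and parietal cell markers. Endothelial, cholesterol synthesis, skeletal muscle and neutrophil-attracting chemokine lists each had 0.646, the estrogen target and MHC class II lists 0.658, the macrophage and B cell lists 0.744, and the T cell list 0.987. When adjusted over the list alone Cxcl1 and Ccl2, both lower, passed in the neutrophil-attracting and the other chemokines. The neutrophil-attracting chemokine, macrophage and T cell lists had a negative median and a positive mean, the estrogen target list had a positive median and a negative mean, and the B cell list had a positive median and mean with a test that pointed down.

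The third comparison set tamoxifen directly against estradiol. No gene passed: limma called 0 genes, and 367 had an unadjusted p under 0.05 (169 higher and 198 lower), fewer than the 964 expected by chance. The groups did not overlap for 3036 genes (15.7%, where chance gives 20%), and 97 of these differed at least 2-fold. Bhmt, which makes methionine from betaine, was not well above background on any estradiol array and stood at least 4.09-fold higher with tamoxifen, and the renin genes Ren1 and Ren2, close copies of each other, stood at 1.72 ± 0.39 and 1.70 ± 0.49 (SE, n = 2 and 3). Frmpd1 stood at 1.09 ± 0.27. Tmeff2 stood at −1.09 ± 0.15. Upk3b, a uroplakin also made by mesothelium, Grin1, a glutamate receptor subunit, and Gdf3, a growth factor of the TGF-β family, were not well above background on any tamoxifen array and stood at least 3.44-fold, 4.49-fold and 2.12-fold lower. Each of these 8 had an adjusted p of 1.00.

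Of the 33 lists 9 passed in this comparison, and 0 did so with an estimated correlation (adjusted p = 0.770 with an estimated correlation for each of the 9) or by fry. The interferon-stimulated genes were lower with tamoxifen (28 of 29, median −0.40, adjusted p = 0.00357), with Ifi44 at −1.06 ± 0.45. Relative to the placebo mean, this list stood at 0.64, 0.34 and −1.10 on estradiol 1 to 3 and at 0.08 and −0.92 on tamoxifen 1 and 2. Its call was lost with normexp, without estradiol 1 and without estradiol 2. The plasma cell markers (8 of 9 lower, median −0.42, adjusted p = 0.00940) and the macrophage and monocyte markers (14 of 19 lower, median −0.16, adjusted p = 0.0317) were lower as well, with Mzb1 at −0.92 ± 0.50 and Fcgr1 at −0.62 ± 0.24. The skeletal muscle markers were lower (7 of 9, median −0.92, adjusted p = 0.0426), and without estradiol 2 the list's mean turned from −0.96 to 0.04 (adjusted p = 0.774). The squamous markers were higher in 21 of 21 genes (median 0.60, adjusted p = 0.00151), with Sprr3 at 0.92 ± 0.68. The mucous cell markers (9 of 10 higher, median 0.25), the xenobiotic metabolism genes (11 of 15, median 0.15) and the cholesterol synthesis genes (19 of 23, median 0.09) were higher, with an adjusted p of 0.0151 each and Gkn1 at 0.42 ± 0.24, Cyp3a11 at 0.52 ± 0.22 and Cyp51 at 0.34 ± 0.16. The adipocyte markers were higher (9 of 11, median 0.32, adjusted p = 0.0426), with Fabp4, a fatty acid binding protein, at 1.01 ± 0.37. No member of any of these lists passed, over all genes or adjusted over the list alone.

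Within slides 1 and 2 the differences were −0.56 and −1.26 (interferon), 0.24 and −1.12 (plasma cell), −0.06 and −0.59 (macrophage), −0.09 and −2.97 (skeletal muscle), 1.97 and −0.54 (squamous), 0.03 and 0.65 (mucous), 0.18 and 0.30 (xenobiotic), −0.17 and 0.15 (cholesterol) and 0.10 and 0.04 (adipocyte). With slide as a block 13 lists passed; the cholesterol and adipocyte calls were lost (adjusted p = 0.0768 and 0.0838). Without estradiol 1 or without estradiol 2, 3 lists passed, without tamoxifen 2, 4, without estradiol 3, 15, and without tamoxifen 1, 17. Without tamoxifen 2 the means of the interferon, plasma cell and macrophage lists turned positive (0.12, 0.06 and 0.02), and none of the 9 calls but the squamous one was kept, which in turn was lost without estradiol 1 (adjusted p = 0.692) or tamoxifen 1 (0.420).

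The always-named genes did not pass between the treatments: Esr1 stood at 0.21 ± 0.34, Cxcl1 at −0.21 ± 0.17, Il1b at −0.14 ± 0.28, Tnf at −0.16 ± 0.62, Ifng at −0.76 ± 0.79, Gast at 0.46 ± 2.67, Atp4a at −0.11 ± 0.57 and Muc6 at 0.72 ± 0.56. The other 24 lists did not pass, with an adjusted p of 0.0512 for T cell markers, 0.0688 for enteric neuron and glia markers, 0.111 for B cell markers and 0.127 each for MHC class II presentation and other chemokines. The remaining 19 lay between 0.137 and 0.846, and among them the parietal cell and heat-shock lists had a negative median and a positive mean.

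The effects of estradiol and tamoxifen were compared across genes. The log2 fold changes against placebo correlated at 0.779 (Spearman 0.734) across 19279 genes, which are not independent replicates. Unchanged groups against the same 3 placebo arrays gave 0.467 on average and up to 0.978 in 100 simulations. The covariance was 0.155 against a simulated mean of 0.0615, a difference of 0.0939, and the highest simulated covariance was 0.320. The sign was the same for 79.2% of genes, against 66.6% simulated on average and 92.9% at most. Of the genes with an unadjusted p under 0.05, 920 were higher and 348 lower with both treatments, where independent lists would share 123 and 34.2 and the simulations shared 110 and 132 on average and 889 and 1958 at most. Opposite directions occurred for 0 genes, a count with no simulated value beside it, and the shared placebo arrays favour equal signs with no effect. Of the values given with a highest simulated one, all but the 920 lay below it. With 3 placebo arrays the controls could not be split into parts of at least 2, so part of the excess over independent lists may come from the shared placebo arrays.

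**Figure D3:**
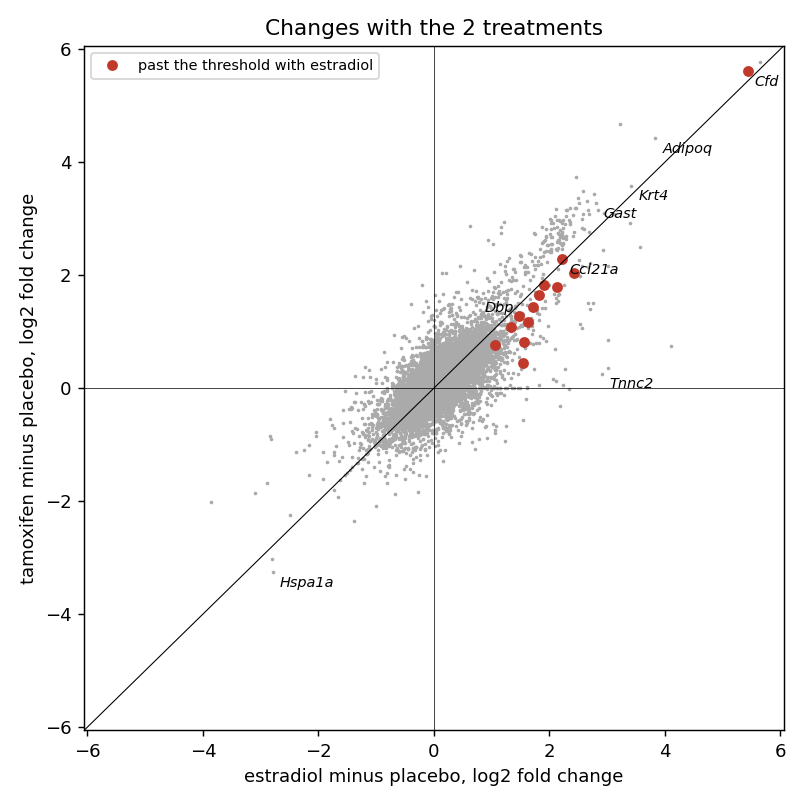
Log2 fold change against placebo with estradiol (x axis) and with tamoxifen (y axis) for 19279 genes, 1 point per gene. Red points are the 13 genes past the threshold with estradiol, and the diagonal marks equal change. Cfd lies at 5.43 and 5.61, and Hspa1a at −2.79 and −3.26.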

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

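Alternatives chosen only after the data had been seen were 0.5 or 2 times the floor, the probes with outlier flags kept and the squamous mean as a covariate. The tests of other splits were planned. Against 13 genes with estradiol, quantile normalization called 4, the series matrix 2, no filter on dim probes 5, every probe by itself 7, array weights 22, and 2 times the floor 3. limma called 0 with normexp (1881 at an unadjusted p under 0.05), with a filter on all arrays (2458), with only the arrays of the 2 groups (2619), with slide as a block (2994) and with the squamous mean as a covariate (1871). The cause was not tested. All 4 genes of quantile normalization were among the 13, as were 10 of the 16 called by median centring. Cfd kept its direction in all 24 alternatives, with log2 fold changes from 4.12 to 6.05 and adjusted p from 0.0425 to 0.380. Against 0 genes with tamoxifen, the series matrix called 1, no filter 4, every probe by itself 1, eBayes with trend and robust 2, and 0.5 times the floor 1; between the treatments no filter called 2 genes and every probe by itself 1, again with no test of the cause. An estimated correlation left 0 lists in each comparison, against 11, 11 and 9. Between the treatments the lists came to 5 without a filter and 15 with every probe by itself, where the cause was not tested.

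With each array left out in turn, where a lone tamoxifen array was assumed to vary like the other groups, the estradiol comparison gave 0 to 36 genes and 9 to 17 lists, the tamoxifen comparison 0 to 0 genes and 7 to 20 lists, and the direct comparison 0 to 0 genes and 3 to 17 lists. Without placebo 3, estradiol gave 36 genes, 18 higher and 18 lower, and 9 lists, and tamoxifen 7 lists; without estradiol 3, estradiol gave 17 lists; without tamoxifen 1, tamoxifen gave 20 lists. The correlation of the effects of both treatments ranged from 0.630 to 0.832. Each of the 10 splits of the 6 estradiol and placebo arrays into 3 and 3 was fitted. The real one gave 13 genes and 11 lists, and the highest other 0 genes and 16 lists. With the real one counted, 1 split gave as many genes and 5 gave at least as many lists. For the genes, 10 splits are too few for a share under 0.05. The number of lists did not set the real groups apart from mixed ones.

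The alternatives were run for 49, 47 and 34 genes of the 3 comparisons, picked by the naming rule and not all described; other genes of the text, such as Alpi, Olfm4, Mki67, Ifit1, Tff3 and Egr1, were not run. Of these values, 1043 of 1168 with estradiol, 1102 of 1119 with tamoxifen and 786 of 806 between the treatments kept their direction and their side of the threshold. Signs changed for 36 values of 11 genes, and 0 of these had passed; the cause was not tested. With normexp Sis was 0.0691 with estradiol, and between the treatments Cyp3a11 was −0.0149, Esr1 −0.34 and Gast −0.24. Between the treatments Gast was −0.90 and Atp4a 0.22 with slide as a block, and −1.17 and 0.11 with array weights, which also gave Ifng 0.0403 with tamoxifen. With the squamous mean as a covariate Esr1 was −0.37 and Gast −0.98 with estradiol, Nos1 −0.11, Esr1 −0.43, Ifng 0.41, Gast −1.78 and Muc6 0.10 with tamoxifen, and Esr1 −0.0521, Gast −0.80 and Atp4a 0.24 between the treatments. With 1 array left out, Il1b ranged from −0.17 to 0.0334 with estradiol. With tamoxifen the ranges were −0.82 to 0.64 for Ifng, −1.47 to 0.41 for Muc6, −0.69 to 0.25 for Il1b, −1.89 to 0.17 for Tnf and −0.33 to 1.11 for Atp4a. Between the treatments they were −1.19 to 0.87 for Tnf, −2.36 to 3.27 for Gast, −0.83 to 0.61 for Atp4a, −1.83 to 0.10 for Tnfrsf17, −0.61 to 0.33 for Il1b and −0.21 to 1.66 for Muc6.

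List calls were also lost under alternatives, and the cause was not tested. The metaplasia call was lost in 9 of 25, among them quantile normalization (adjusted p = 0.136), the series matrix (0.0956), the filter on all arrays (0.0684), array weights (0.0541) and 2 times the floor (0.0597). The intestinal call was lost in 5, with normexp (0.0793), that filter (0.184) and 2 times the floor (0.0728), the adipocyte call in 6, with that filter (0.242), every probe by itself (0.128) and 2 times the floor (0.0746), and the cell cycle call in 6, with the series matrix (0.0507) and array weights (0.193). With tamoxifen the immediate-early call was lost in 11 of 25, among them quantile normalization (0.263), the series matrix (0.148), no filter (0.0636), every probe by itself (0.0883) and 0.5 times the floor (0.0506). The endocrine call was lost in 10, with the filter on all arrays (0.0584), the mean of a gene's probes (0.0574), array weights (0.0911) and 0.5 times the floor (0.0506), the intestinal call in 6, with no filter (0.140), the filter on all arrays (0.135) and 2 times the floor (0.0637), the mast cell call in 6, with no filter (0.0948) and 2 times the floor (0.0508), and the adipocyte call in 2, with the filter on all arrays (0.0584). Between the treatments the adipocyte call was lost in 14 of 25 and the skeletal muscle call lost in 11 and turned in 1; of the other 7 calls, each was lost in 2 to 6, and 4 of them turned in 1 more.

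Residuals of arrays on the same slide correlated at −0.264 to 0.369 (median 0.153, 7 pairs, 6 of them positive) and those of other pairs at −0.383 to 0.383 (median −0.109, 14 pairs). Since not every pair lay above 0.1 the shared number was not taken as a pairing, although the 2 tamoxifen residuals mirror each other and fix part of these values. The signal over background limits genes near the floor, such as Otor and Rapgef4, whose log2 fold changes with estradiol ranged from 0.587 to 2.71 and from 0.409 to 1.97 and whose adjusted p ranged from 0.000627 to 0.507 and from 0.0263 to 0.620.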

Other observations

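The tests of dilution, slide and normalization below were chosen only after the result was seen. The dilution limit was raised from 2 SE to the 95% limit of t afterwards. The squamous slide test was changed as well: a limit of 2 SE had argued against a difference between slides. So had the share of the shift that the block removed, which was dropped because the layout fixes it for estradiol. The limit of t used here was not reached. The condition on the adipose test was added after its value was seen, and replaced once.

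Clock genes outside the fixed lists were measured because Dbp stood high with tamoxifen. With tamoxifen Hlf stood at 1.24 ± 0.25, Tef at 1.12 ± 0.22, Per3 at 1.19 ± 0.27 and Nr1d2 at 0.99 ± 0.19, while Arntl, of the opposite phase, stood at −0.78 ± 0.19. None passed (adjusted p from 0.365 to 0.383), and these 5 were named after their values were seen. The signs fitted Dbp's phase in 12 of 12 clock genes with tamoxifen and 11 of 12 with estradiol, with signed medians of 0.797 and 0.458. At an unadjusted p under 0.05 there were 6 and 5 of the 12, and with tamoxifen Clock (−0.08 ± 0.24) and Cry1 (−0.08 ± 0.53) lay near 0.

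Dbp with tamoxifen: the differences within slides, where a difference between slides that moves its arrays alike cancels, were 1.56 and 1.52. The choice of Dbp as a gene without overlap between the groups fixes their sign, so they are no separate evidence. Another time of day at collection remains a candidate explanation, since the other clock genes had a signed median of 0.797 (0.781 without Ciart, which stood at the floor on all placebo arrays), above the 0.3 set in advance. Collection times are not given in the sources used here. A rhythm shifted by the treatment would give the same values and was not tested.

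Squamous forestomach markers with both treatments: a lower share of glandular mucosa, raising every other tissue alike, was tested against the fibroblast mean alone. The squamous mean exceeded it by 1.99 (SE 0.633) with estradiol and by 2.44 (SE 0.707) with tamoxifen, more than 2.57 SE each. With slide as a block the ratios were 2.67 and 2.57, short of the limit of 3.18. With estradiol the fibroblast mean stood at −0.23, whereas the smooth muscle and neural means rose by 0.64 and 1.08. The squamous mean was not tested against those 2 lists, so the test cannot decide. It covers only an equal rise of the other tissues. Less mucosa that raises each tissue by its own ratio was not tested and stays open. More squamous forestomach in the strips of treated mice may be the cause. Cornified epithelium genes outside the list had medians of 1.57 with estradiol and 2.15 with tamoxifen, with 20 and 21 of 25 higher. At an unadjusted p under 0.05, 11 were higher and 2 lower with estradiol, and 14 and 0 with tamoxifen. The 2 lower ones were Anxa8 (−1.07 ± 0.32) and Sprr2a1 (−0.62 ± 0.16). Every slide held an estradiol and a placebo array, so a difference between slides that moves its arrays alike cancels between these groups. The estradiol shift was 1.76 with and without the block. With tamoxifen the differences within slides 1 and 2 were 1.82 and 1.82. With slide as a block the shifts were 1.76 (SE 0.868) with estradiol and 2.15 (SE 1.02) with tamoxifen. At 2.03 and 2.11 SE against a limit of 3.18 they were not clear of the spread between arrays, so this test decided nothing. On slide 1 the estradiol difference was −0.15. A change in squamous tissue made by the treatments may raise the same genes and was not tested.

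Cfd and Adipoq with both treatments: the background correction or normalization is argued against as the cause for Cfd, since the lowest log2 fold change of Cfd among them was 4.12. Adipoq was not part of that test. Over all alternatives it ranged from 2.00 to 4.83 with estradiol and from 2.29 to 5.42 with tamoxifen. Attached adipose tissue cannot be told apart from a change within the stomach. Adipose genes outside the list had medians of 0.263 with estradiol and 0.153 with tamoxifen. Dim genes among them stood on both sides of 0 with estradiol, such as Npr3 (−0.46 ± 0.30) and Sncg (1.34 ± 0.22). The bound set in advance (under 0.5) counts the medians against attached fat. That bound assumed that all would move alike, whereas added fat may raise each gene by its own ratio of levels in fat and stomach, not measured here, and at an unadjusted p under 0.05 the 19 genes went both ways (2 higher and 2 lower with estradiol, 3 and 1 with tamoxifen). An effect of the treatments on fat cells was not tested.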
